A study of Arabidopsis thaliana with 20 samples.

How the data were processed

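DNase I-seq was done in 14 samples of Arabidopsis thaliana seedlings in 7 conditions, and RNA-seq in 6 samples, which are not analysed here. Per the labels' protocols, nuclei of an INTACT line in the Col-0 background were captured through biotin, treated with 45 units of DNase I for 3 min at 25 °C, and small fragments with a cut at both ends were sequenced. Per the labels, each library is listed as a single-end and a paired-end sample. The 2 peak files of each library were checked to be byte-identical, so they count once and there is 1 library per condition. No error between replicates can be given, and no p-value between conditions is given.

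Per the submitters' processing notes, the tools were Bowtie 0.12.7 and CASAVA 1.8.2 and the genome build was TAIR10. The peak caller, its threshold and any read filter are not given in the sources used here. The series description states that samples subsampled to equal read depth are included, and the labels do not mark which samples these are. Each deposited file has 10 columns in the narrowPeak layout and no header, and more than 99% of peaks are 150 bp wide. Its signal column, as deposited, holds a whole number per peak whose minimum and median differ between libraries, with no normalization seen. It was used to rank, filter and describe peaks within a list and never compared between lists as a value. The other column described is the authors' −log10 p-value per peak, which ends at 324 in every deposited list, where 11.27% (dark) to 39.45% (spray control) of peaks stand, so it was not used for ranking. The other columns were not used.

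Depth can be described only by the lists: 26712 to 34637 nuclear peaks per library, covering 4.01 to 5.197 Mb. The spray control list held 34254 peaks with those of the organelles. Wilson intervals at the 95% level cover counting error over peaks only, and peaks are not independent molecules.

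Gene positions came from the RefSeq annotation of TAIR10.1, whose 5 nuclear chromosomes carry 27444 protein-coding genes. Coordinates are 1-based. The build was checked by moving all peaks by 5000 bp: the share of dark peaks with a midpoint in a promoter window went from 59.8% to 27.8% and that of LD control peaks from 57.6% to 28.4%, near the 25% of the genome. A promoter window ran from 1000 bp upstream to 200 bp downstream of an annotated gene start. Each peak was placed by its midpoint, in the order promoter window, 5′ UTR, CDS, intron, 3′ UTR, other sequence.

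A peak was called gained when it overlapped no peak of the reference list by at least 1 bp, and lost for the reverse. The 4 main comparisons were heat shock against LD control and 30 min, 3 h and 24 h of light against dark. The comparison of spray control with LD control served as a yardstick without heat or a change of light, though not a replicate pair, since the spray and the handling of organelle peaks differ, and dark and 24 h of light were also compared with the LD control. The 3 light comparisons share the dark library, so no overlap of their gained or lost genes was computed.

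Gene lists were fixed by hand before the data were examined, as were the windows, the motifs, the comparisons, the naming rule and most of the other settings tried. There were 19 lists with 347 genes: heat chaperones, other heat-induced genes, heat shock factors, unfolded protein response, light harvesting and photosystems, carbon fixation, chlorophyll synthesis, light signalling, early light protection and flavonoids, circadian clock, auxin and cell wall growth, cold, ABA, touch and wound response, housekeeping, seed storage, markers of root, of guard cells, of epidermis and trichomes, and of vascular tissue, and cytosolic ribosomal proteins. The last was taken from product names in the annotation. CRT2 was dropped, since the annotation gives its identifier another symbol. A list's count is the number of members whose promoter window touches a gained or lost peak. It was ranked among 10000 random lists of equal size matched on the number of promoter peaks in the reference list (0, 1, 2 or more), and stands apart when at most 2.5% of them reach it. With 19 lists, 2 directions and 4 comparisons there are 152 such counts, of which 2.5% would stand apart by chance. Neighbouring genes can share a peak. Percentiles describe these libraries.

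Named genes follow a rule: up to 10 members by signal from each list that stands apart, up to 3 from each other list, the 10 genes with the strongest gained or lost promoter peaks, and 15 genes always named. Genes named outside this rule are marked as chosen after their values were seen.

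Motifs were searched on both strands in the 150 bp around each midpoint: heat shock elements of 2 and 3 units, G-box, I-box, evening element, site II element, telo-box, W-box and dehydration-responsive element, with letter-rearranged controls for all but the 3-unit element. Shares in gained or lost peaks were ranked among 10000 sets drawn with replacement from retained peaks, matched on GC decile and promoter position.

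Peaks over the transcribed span of genes were counted after the planned window with the gene body had been seen, with random lists matched on gene length and reference peaks over the span. Another close genomic match means at least 90% identity over at least 75 bp elsewhere in the genome, found with BLAST+ 2.17.0. Nuclear copies of mitochondrial DNA were mapped at 95% identity over at least 300 bp.

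Other settings fixed in advance were an overlap of at least 50% of the shorter peak, lists of equal length (26712 peaks of highest signal each), the upper 50% by signal, the spray control or both controls as the reference, a window of 500 bp upstream to 100 bp downstream, the gene body with 1000 bp upstream, random lists or sets without matching, and motifs over the whole peak. Settings added after seeing the data left out peaks with another close match, peaks within 150 bp of a peak of the other list or copies of mitochondrial DNA, used lists of equal length for gene lists and locations, counted each peak for 1 member, or matched motif sets on signal decile, 3 GC classes in place of 10, and position.

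The steps were tested on simulated data. Overlap calls matched bedtools for all of 12260 simulated peaks, with 0 called differently. For heat shock against LD control with 27444 genes, lists of 30 genes with no added effect reached the threshold in 1.4% of 500 simulations and lists with 3-fold as many gained genes in 68.6%; for lists of 40 genes these were 1.2% and 83%. In 4000 simulated sequences all planted motifs were found (100%), and 3% of 300 sets without planted motifs reached the threshold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.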

Results

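DNase I-seq marks open chromatin by sequencing the small fragments that the nuclease DNase I releases from nuclei. It was done here on 7-day-old Arabidopsis thaliana seedlings of a Col-0 line whose nuclei carry a biotin tag for their capture (INTACT). The light series holds seedlings grown in the dark and dark-grown seedlings after 30 min or 3 h of light or 24 h in the light/dark cycle, called 24 h of light here. The heat series holds seedlings of a light/dark cycle (16 h light at 22 °C, 8 h dark at 20 °C) as an untreated LD control, as a spray control 3 h after a spray with 0.5% ethanol, and after a heat shock of 30 min at 45 °C. Each of the 7 conditions has 1 library, listed as 2 samples with byte-identical peak files, so 14 samples gave 7 peak lists. No difference between conditions has a replicate check. Shares carry 95% Wilson intervals, which cover counting error only.

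The nuclear peak lists held 28917 peaks in the dark, 28824 after 30 min of light, 31336 after 3 h and 26712 after 24 h. They held 34637 peaks in the LD control, 33780 in the spray control and 32755 after heat shock. Read depths were not used here. The authors' signal, a whole number per peak, had a median of 148 in the dark, 417 in the LD control and 1036 in the spray control, so it was compared only within a list. The lists covered 3.366% (24 h of light) to 4.362% (LD control) of the nuclear genome. Between 57.6% (LD control) and 61.7% (24 h of light) of peaks lay in promoter windows, from 1000 bp upstream to 200 bp downstream of a gene start, which take up 25% of nuclear bases.

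Most open regions were shared between conditions. Merging the 7 lists gave 47780 regions, of which 18456 (38.6%) held a peak in every condition and 9417 (19.7%) in 1 condition. In the light series, 21900 of 36809 regions (59.5%) held a peak at all 4 times, and 92.6% of these also did in the LD control. Regions seen after 3 h of light and at no other time of the series numbered 3184 (8.65%), and 46.5% of them were peaks in the LD control (44.8 to 48.3%). A further 821 regions (2.23%) had no peak in the dark and a peak at all 3 times in light, and 68.3% of these were peaks in the LD control.

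**Figure D1:**
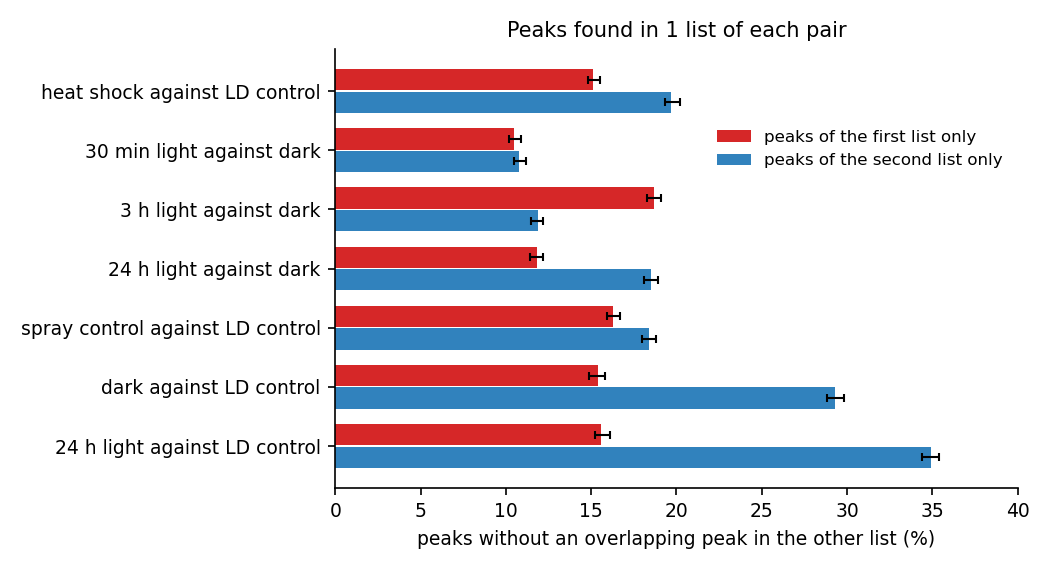
Percent of peaks of each list without an overlapping peak in the other list of the pair (horizontal axis, percent; bars with 95% Wilson intervals, 1 library per condition), for 7 pairs; red bars count the list named before "against" and blue bars the list named after it. Shares ran from 10.5% (30 min of light against dark) to 34.9% (LD control peaks missing after 24 h of light), and the pair of LD control and spray control gave 16.3% and 18.4%.

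The heat shock comparison asked where chromatin opened or closed within 30 min at 45 °C. After heat shock, many heat chaperone genes, whose products hold or refold damaged proteins, had new peaks along their transcribed spans. Of 30 listed genes, 13 gained at least 3 peaks there, while 3 small heat shock protein genes gained 0 and 3 had no more peaks than in the LD control. Together the listed genes carried 96 peaks over their transcribed spans in the heat shock list, against 18 in the LD control, 22 in the spray control and 16 to 20 in the light series. HSP101 (AT1G74310, chromosome 1, 27936508 to 27940369, minus strand), a protein disaggregase, had 1 peak over its span in each of the other 6 lists, at its start, and 8 after heat shock, from 27936361 to 27940330. HSP70 went from 1 peak in the LD control to 5, HSP70B from 1 to 6, BAG6 from 1 to 6, HOP3 from 1 to 6, plastid CLPB3 from 0 to 4 and HSP90.1 from 0 to 3.

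**Figure D2:**
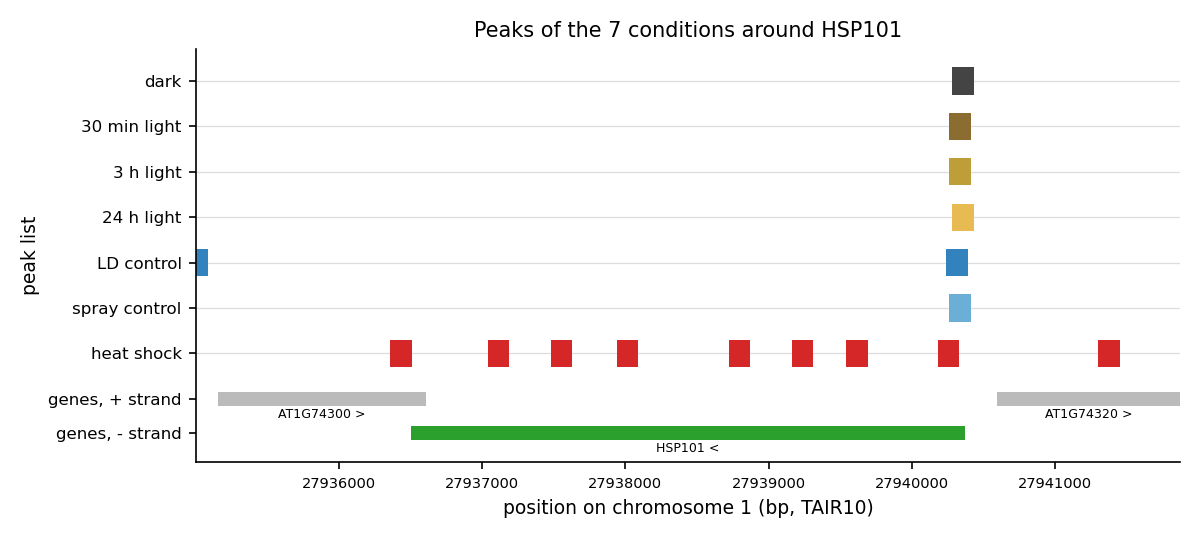
Peaks of the 7 lists around HSP101 on chromosome 1 (horizontal axis, TAIR10 position; each box is 1 peak; genes are drawn with their direction). Heat shock has 8 peaks over HSP101 and each other list has 1, at its start.

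A heat-gained peak, meaning one that overlaps no LD control peak, lay over the span of 27 of the 30 chaperone genes (random lists matched on length and LD peaks, mean 1.78; percentile 100). These were 73 distinct peaks, 42 with their midpoint in coding sequence and 5 in introns. Of the 73, 54 were in the upper 50% of the heat shock list by signal and 2 had another close genomic match, which left 26 genes. In the spray control 6 of the 30 genes had such a peak (mean 3.08, percentile 92.36). This count over the transcribed span was chosen after a planned wider window, the gene with 1000 bp upstream, had given 27 of 30 genes (mean 3.77, percentile 100).

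Heat shock factors, a transcription factor family that includes activators of chaperone genes, had fewer such peaks. A gained peak lay over the span of 7 of 21 (mean 1.29, percentile 99.99), 2 of them had 2 and none had 3. The list carried 20 peaks in the LD control, 22 in the spray control and 28 after heat shock, and HSFB1 had 3 both in the LD control and after heat shock. Spray-gained peaks over spans put 3 other lists at percentiles of 99.21 to 99.73. Without heat, peaks gained after 24 h of light against the LD control lay over 4 of 21 heat shock factors (mean 0.971, percentile 98.62). They also lay over 5 of 30 chaperones (mean 1.4, percentile 98.82). After heat shock HSFA2 and HSFA7A gained the most. HSFA2, a heat-induced activator, had 0 peaks over its span in the LD control, 1 in the spray control and 2 after heat shock. HSFA7A went from 1 in both controls to 3. Other heat-induced genes had 3 of 6 (mean 0.39, percentile 99.6), namely MBF1C, DREB2A and GOLS1, but no larger total: that list carried 5 peaks in the LD control, 9 in the spray control and 6 after heat shock. MBF1C and GOLS1 had as many peaks after heat shock as in the LD control, and DREB2A had 0 in the LD control, 3 in the spray control and 1 after heat shock. Across all genes, 27 carried at least 3 gained peaks over their span after heat shock, 13 of them listed chaperones. The spray control had 29 such genes, 0 of them listed chaperones.

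**Figure D3:**
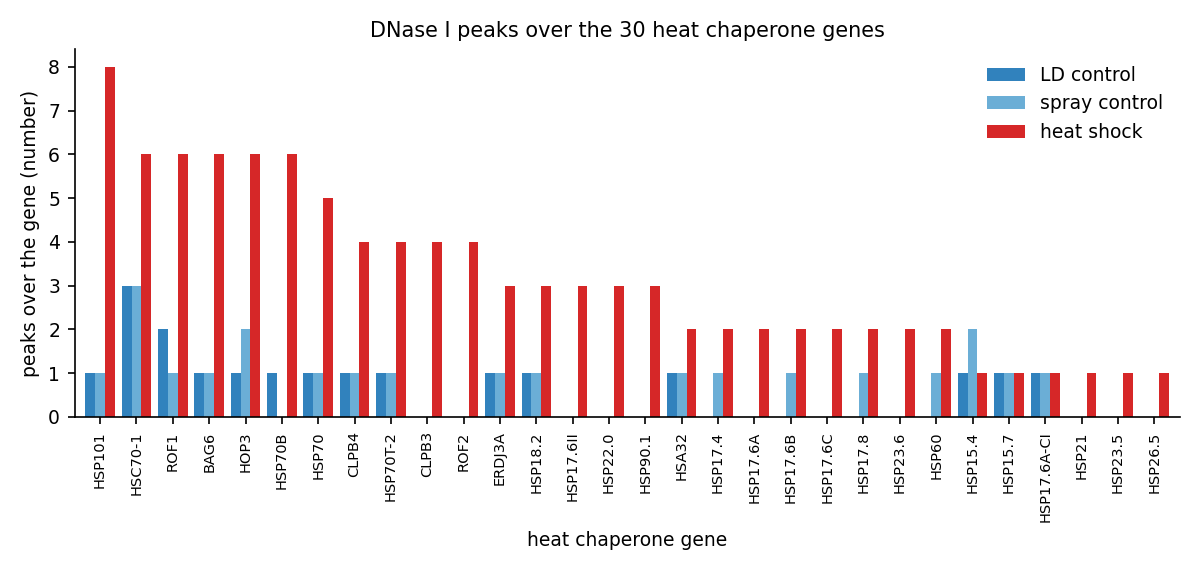
Number of peaks (vertical axis) over the transcribed span of 30 heat chaperone genes (horizontal axis) in the LD control, spray control and heat shock lists. Each condition has 1 library. The totals are 18, 22 and 96, and HSP101 has the most after heat shock, 8.

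In promoter windows, the measure fixed in advance, heat chaperones gained peaks at 9 of 30 genes (mean of matched random lists 2.6, percentile 99.96). The strongest lay at HSP17.6B (AT2G29500, chromosome 2, 12633861 to 12634010), a small heat shock protein gene, with a signal of 1844 (percentile 98.9 of the list). HSP17.6A (chromosome 5, 3884681 to 3884830, signal 1296) and HSP17.6C (chromosome 1, 19980401 to 19980550, signal 1284) each lost a peak of all 6 other lists just upstream, so their peaks lay at new positions. ROF2, a chaperone-binding isomerase, gained a peak with signal 1027 and ERDJ3A, a co-chaperone of the endoplasmic reticulum, one with signal 838. HSP17.6II, HSP60 and HSP26.5 gained peaks too, and the gained promoter peak of HSP101 was weak (signal 130). Without heat, HSP60 also gained a promoter peak in the spray control against the LD control. HSP17.6II and HSP26.5 did so after 24 h of light, against both the dark and the LD control. Apart from HSP101, each gene with a gained peak had one that also touched its transcribed span, so this count is not separate from the count over spans. The gained peak of HSP101 lay within the span of its neighbour AT1G74320. Chaperones lost peaks at 7 genes (mean 4.05, percentile 90.87), among them HSP90.1 and HOP3. Members with any promoter peak did not rise in number: 27 in the LD control, 27 in the spray control and 26 after heat shock. Without gained peaks within 150 bp of an LD control peak the gained count was 5 (mean 1.81, percentile 96.84), and in a narrow window of 500 bp upstream to 100 bp downstream it was 4 (percentile 94.01), both below the threshold, which 2.5% of random lists pass.

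Auxin and cell wall growth genes, which drive cell elongation, gained peaks at 7 of 31 members after heat shock (mean 2.55, percentile 98.78). They were EXPA8, EXPA5, XTH17, XTH33, YUC2 and the neighbours SAUR22 and SAUR23, which share 1 peak. All these peaks were weak: restricted to the upper 50% by signal the count was 0, and with lists of equal length it was 2 (percentile 31.18). A stricter overlap put the list at 93.95 and the distance of 150 bp at 92.94, both below the threshold.

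The other lists stayed below the threshold for peaks gained in promoter windows after heat shock against the LD control. Vascular markers passed it with both controls merged and with lists of equal length, guard cell markers in the upper 50% by signal, and heat shock factors in the window with the gene body. Heat shock factors gained at 1 of 21 members (HSFA7A, signal 1054), other heat-induced genes at 1 of 6 (MBF1C) and genes of the unfolded protein response at 0 of 12. Light harvesting and photosystem genes gained at 5 of 40, carbon fixation at 1 of 10 (RCA), chlorophyll synthesis at 1 of 16, light signalling at 5 of 30 and early light protection and flavonoid genes at 2 of 8. The clock gained at 1 of 17, cold, ABA, touch and wound response at 2 of 32, housekeeping at 1 of 17, seed storage at 1 of 9 and cytosolic ribosomal proteins at 2 of 10. Among cell type markers, the root list gained at 2 of 20, guard cells at 3 of 12, epidermis and trichomes at 0 of 12 and vascular genes at 4 of 14 (percentile 96.7).

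No list stood apart for promoter peaks lost after heat shock against the LD control. Among lost LD control peaks that overlap a spray control peak, heat chaperones and early light protection and flavonoid genes did. A stricter overlap also set the chaperones apart, and random lists without matching the light protection genes. Early light protection and flavonoid genes lost peaks at 5 of 8 (mean 2.37, percentile 95.47): ELIP1, ELIP2, the chalcone synthase gene TT4, FLS1 and MYB111. Of these, ELIP1 and ELIP2 also gained promoter peaks after heat shock. Clock genes lost them at 2 of 17 (TOC1 and PRR7; mean 4.56), as few as in 11% of random lists. Among light signalling genes 8 of 30 lost a peak (mean 8.21), including BBX22 (signal 1215) and the photoreceptor gene PHYA (signal 862).

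Over the whole genome, 4962 heat shock peaks (15.1%, 14.8 to 15.5%) overlapped no LD control peak, and 6839 LD control peaks (19.7%, 19.3 to 20.2%) overlapped no heat shock peak. The pair of spray and LD control gave 16.3% (15.9 to 16.7%) and 18.4% (18 to 18.8%). This pair is not free of differences: the plants had an ethanol spray and 3 h of waiting, and the spray list alone held organelle peaks (474). The spray list also had a median signal of 1036, against 417 in the LD control and 424 after heat shock. In nuclear copies of mitochondrial DNA it held 58 peaks, and the LD control and heat shock lists held 0. In the upper 50% by signal the heat shock pair gave 5.44% and 6.16% and the spray pair 4.42% and 4.43%. Gained peaks touched promoter windows of 2389 genes (8.7%) and lost peaks those of 3610 (13.2%).

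The strongest gained peaks often sat beside a lost one. Of 97 gained peaks in the top 10% by signal, 67 (69.1%) lay within 150 bp of an LD control peak and 49 (50.5%, 40.7 to 60.3%) within 150 bp of one that heat shock lost. LBD37, a regulator of nitrogen responses, lost the peak at 26906541 to 26906690 on chromosome 5 and gained one at 26906741 to 26906890. The corepressor gene TPL, the transcription factor gene RAV1 and the citrate synthase gene CSY2 had such pairs too. MBF1C, a heat-induced coactivator, lost a peak centred 49 bp downstream of its start and gained one at 249 bp, the position it also had after 30 min, 3 h and 24 h of light.

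A heat shock element of 3 units, the binding site of heat shock factors, occurred in 37 of 4962 heat-gained peaks (0.746%, 0.541 to 1.03%). Retained peaks matched on GC content and position held it in 0.204% on average (3.66-fold, percentile 100). In the upper 50% by signal 5 of 890 gained peaks held it (2.57-fold, percentile 95.37), below the threshold. It occurred in 6 of 6839 lost peaks (0.489-fold), and spray-gained peaks held it at 1.07-fold. Of the 37 heat-gained peaks with it, 23 were in the heat shock list only. The rest were also peaks in a list without heat, such as those at PCME and EMB1241 in the spray control. Of the 37 peaks, 17 touched a promoter window and 1 of these belonged to a listed gene, ERDJ3A, with TTCGAGAAATTTC at 2737414 to 2737426 on chromosome 3. The shorter element of 2 units stood at 1.19-fold after heat shock (percentile 99.83) and at 1.44-fold in spray-gained peaks (percentile 100). In heat-gained peaks of the upper 50% by signal it stood at 1.26-fold (percentile 94.14) and with sets matched on signal, and on 3 GC classes in place of 10, at 1.12-fold (percentile 96.72), both below the threshold. In heat-lost peaks the 2-unit element stood at 1.15-fold (percentile 99.71), close to its fold in gained peaks. With the letters reversed, as a control, the 2-unit element stood at 1.02-fold in heat-gained and 1.52-fold in heat-lost peaks (percentile 100). The 3-unit element had no such control.

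The light series asked how chromatin of dark-grown seedlings responds to light. After 30 min of light the lists differed least of the main comparisons: 3034 peaks (10.5%, 10.2 to 10.9%) overlapped no dark peak and 3124 dark peaks (10.8%, 10.5 to 11.2%) were not found. Auxin and cell wall growth genes lost promoter peaks at 9 of 31 members (mean 3.26, percentile 99.76). None of these peaks was in the upper 50% by signal, and in the narrow window the list stood at 93.97, below the threshold. These included the auxin response repressors IAA3, IAA6, IAA17 and IAA29, the wall-loosening enzymes XTH19 and XTH33, the ethylene synthesis gene ACS8, and SAUR22 with SAUR23, which share 1 dark peak. IAA6, IAA17, IAA29 and ACS8 had a peak at the same place again in the LD control. Gained peaks at this time reached 4 of 40 light harvesting and photosystem genes (mean 2.65, percentile 73.03) and 3 of 30 light signalling genes (percentile 77.5). F3H, a flavonoid enzyme gene, and RBCS1A, which encodes the small Rubisco subunit, gained a peak that every list but the dark one held.

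After 3 h of light, promoters of photosynthesis genes held peaks where the dark list had none. Light harvesting and photosystem genes gained peaks at 13 of 40 members (mean 5.1, percentile 99.93). Among them were the antenna genes LHCB1.1, LHCB2.1, LHCB2.2, LHCB2.3, LHCB3, LHCB5 and LHCA5, the neighbours LHCB1.4 and LHCB1.5, the photoprotection gene PSBS, PSAG, PSAH2 and FNR2. LHCB3 (AT5G54270), for example, gained a peak at 22038201 to 22038350 on chromosome 5 (signal 136), also found after 24 h and in the 3 lists of the heat series. Of the 14 distinct peaks, 2 were already seen after 30 min and 11 were peaks in the LD control. All 14 lay in the lower 50% of the 3 h list by signal, so the count over the upper 50% was 0. With lists of equal length it was 7 of 40 (mean 3.47, percentile 94.5).

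Light protection and light signalling genes gained promoter peaks at the same time. Early light protection and flavonoid genes did so at 5 of 8 members (mean 1.05, percentile 99.89): ELIP1 and ELIP2, which protect thylakoids, the flavonoid enzymes F3H and TT4, and their regulator MYB12. ELIP1 gained a peak at 8086201 to 8086350 on chromosome 3 (signal 298 in the 3 h list). It lost a dark peak at 8086661 to 8086810 (signal 74 in the dark list), so it had 1 promoter peak at both times. In the narrow window the list stood at 93.2, below the threshold. Light signalling genes did so at 7 of 30 (mean 2.69, percentile 98.58), namely BBX24 (signal 509), RUP1, PIF5, BBX25, SPA4, the HY5 homologue HYH and PAR2. The light signalling count was 4 (percentile 91.36) without peaks within 150 bp of a dark peak, and 7 with a mean of 4.08 (percentile 89.59) against unmatched random lists. It stood at 69.28 with a stricter overlap and at 78.25 in the narrow window.

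**Figure D4:**
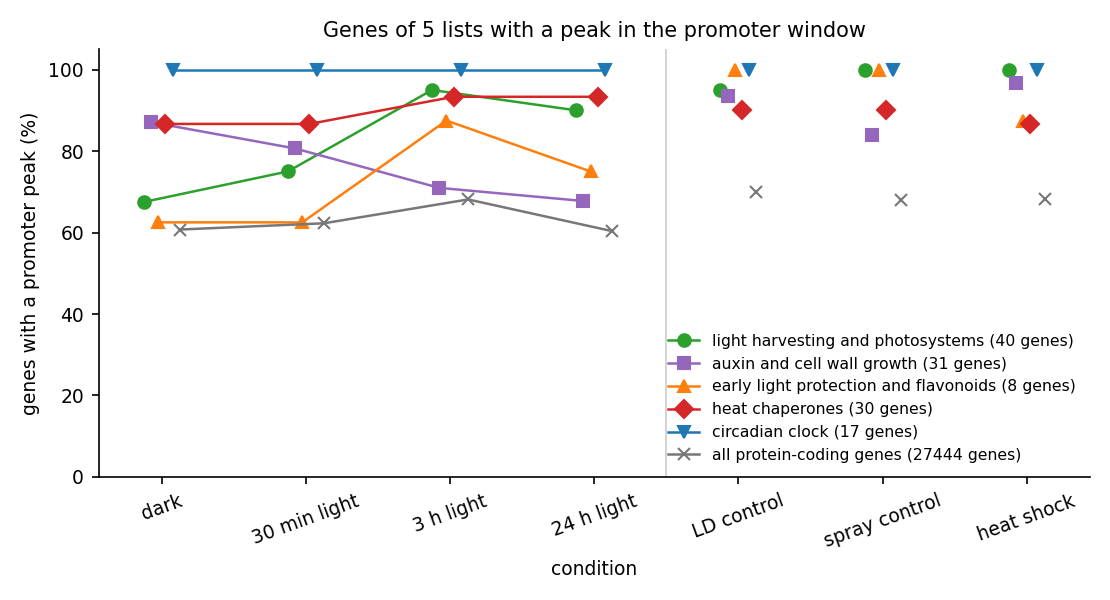
Members of gene lists with at least 1 promoter peak (vertical axis, percent of members; each point is 1 library) in each of the 7 conditions, with all protein-coding genes as crosses. Light harvesting and photosystem genes go from 27 of 40 in the dark to 38 after 3 h of light, and auxin and cell wall growth genes from 27 of 31 to 22.

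Growth genes moved the other way after 3 h. Auxin and cell wall growth genes lost promoter peaks at 11 of 31 members (mean 3.66, percentile 99.97), among them all 6 of the tandem genes SAUR19 to SAUR24 on chromosome 5, which promote cell expansion. The dark peaks at SAUR19 (5963601 to 5963750), SAUR20, SAUR21 and SAUR24 were still called after 30 min, had no counterpart after 3 h and 24 h, and were present in the LD control. IAA3, IAA6, XTH19, XTH33 and ACS8 made up the rest. SAUR copies resemble each other and SAUR20's peak had another close genomic match; without such peaks the count was 10 (percentile 99.92). These dark peaks were in the lower 50% by signal, and the count over the upper 50% was 0.

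**Figure D5:**
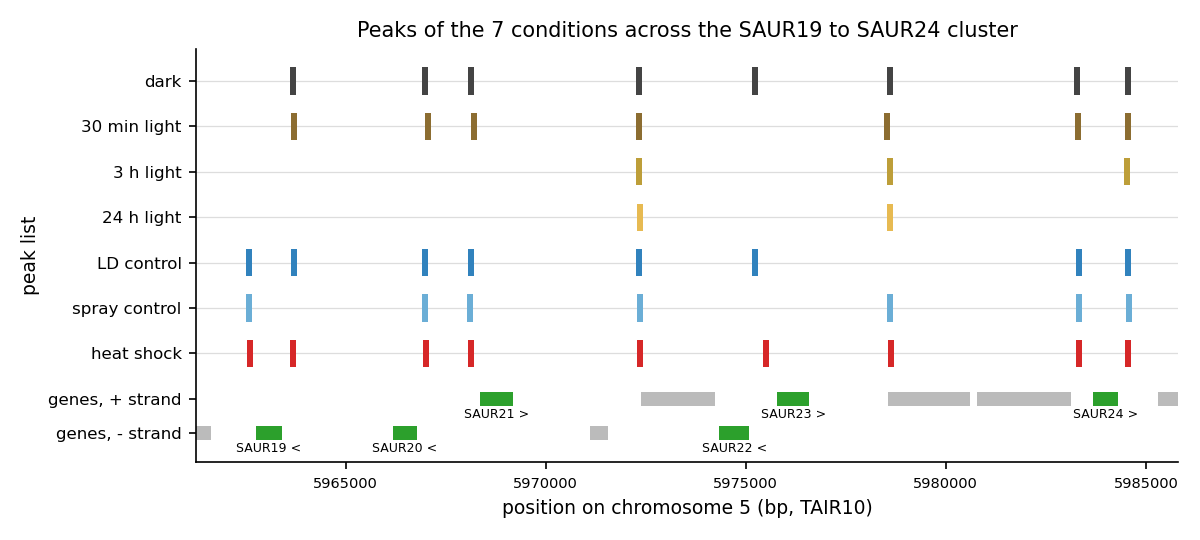
Peaks of the 7 lists across the SAUR19 to SAUR24 cluster on chromosome 5 (horizontal axis, TAIR10 position from 5961273 to 5985808; each box is 1 peak). The promoter peaks of SAUR19, SAUR20, SAUR21 and SAUR24 are called in the dark, after 30 min and in the LD control, and not after 3 h or 24 h of light.

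The 3 h list gained more than it lost: 5859 peaks (18.7%, 18.3 to 19.1%) overlapped no dark peak and 3430 dark peaks (11.9%, 11.5 to 12.2%) were not found. Gained peaks touched promoter windows of 3726 genes (13.6%). With lists of equal length both shares came close, at 13.4% and 13.3%. The strongest gained promoter peak belonged to GI, a clock gene (chromosome 1, 8061061 to 8061210, signal 830, percentile 99.5). The spray control shared it and the dark, 24 h and LD lists did not. HSFA6A gained a peak (signal 595) found in no other condition. Root markers gained peaks at 6 of 20 (mean 3.42, percentile 89.06), carbon fixation at 3 of 10 (percentile 88.1) and heat chaperones at 2 of 30 (percentile 15.46).

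After 24 h of light the photosystem, light protection and growth groups passed the threshold too, each with settings that ended the call. Both times were compared with the same dark library, so the 24 h counts are no independent repeat of those at 3 h. Light harvesting and photosystem genes had gained peaks at 9 of 40 (mean 2.87, percentile 99.89): LHCB2.1, LHCB3, LHCB1.1, LHCB1.3, LHCB1.4, LHCB1.5, LHCA5, PSAH2 and FNR2. With a stricter overlap this list stood at 96.94. Early light protection and flavonoid genes had them at 4 of 8 (mean 0.59, percentile 99.87), without MYB12, and stood at 91.01 in the narrow window. ELIP1 again lost its dark peak. Auxin and cell wall growth genes had lost peaks at 12 of 31 (mean 5.87, percentile 99.57), again with all 6 SAUR genes and now with IAA17 and XTH17. Without peaks that have another close match this count was 10 (percentile 96.06), and with a stricter overlap the list stood at 93.36, both below the threshold. Over transcribed spans, gained peaks reached 8 of 40 photosystem genes (mean 1.79, percentile 99.96) and 5 of 30 heat chaperones (mean 1.54, percentile 98.58). Light signalling genes gained promoter peaks at 5 of 30 (mean 1.97, percentile 95.75), with BBX22 (signal 520) and HYH (signal 286) among them. The upper 50% by signal again held 0 of the photosystem and auxin peaks.

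At 24 h, 3152 peaks (11.8%, 11.4 to 12.2%) overlapped no dark peak and 5349 dark peaks (18.5%, 18.1 to 18.9%) were not found; with lists of equal length both shares were 14.9%. The strongest gained promoter peaks lay at IVD (signal 857), an enzyme of leucine breakdown, and at the transcription factor genes bZIP1 (signal 715) and RAV1 (signal 698). ZAT12, a stress-induced zinc finger gene, gained a peak (signal 702) and lost 2 (signals 551 and 520). UBQ10, a polyubiquitin gene used as a housekeeping control, lost a peak of signal 681. Of the 72 gained peaks in the top 10% by signal, 67 (93.1%) lay within 150 bp of a dark peak. After 3 h this held for 64 of 72 (88.9%) and after 30 min for 33 of 40 (82.5%).

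Short motifs were counted in the light-gained peaks too. Folds of this size can arise without a binding site, since letter-rearranged controls reached up to 1.63-fold (percentile 99.59). Among these controls, the reversed site II element stood at 1.31-fold (99.92) in peaks gained at 30 min and 1.32-fold (100) at 3 h. The telo-box, common in promoters of ribosomal and growth genes, was more frequent than in matched retained peaks among peaks gained after 30 min (1.54-fold, percentile 99.96), 3 h (1.46-fold, 99.99; 144 of 5859 peaks, 2.46%) and 24 h (1.48-fold, 99.82). At 24 h it stood at 0.948-fold with sets matched on signal and on 3 GC classes in place of 10, and at 1.07-fold without matching (percentile 68.29), so that call depends on the matching. The reversed control of the telo-box stood at 1.08, 0.878 and 0.985-fold. In the upper 50% by signal the telo-box stood at 1.52, 0.602 and 0.684-fold. The evening element, bound by clock proteins, was more frequent among peaks gained at 24 h (60 of 3152, 1.9% against 1.25%; 1.52-fold, percentile 99.83), and its reversed control stood at 1.12-fold. Peaks gained at 3 h also held the 2-unit heat shock element at 1.23-fold (percentile 100), above its 1.19-fold after heat shock, and the dehydration-responsive element at 1.17-fold (99.94). G-box and site II elements were less frequent in gained and in lost peaks of every main comparison, as in the spray pair. After heat shock they stood at 0.547-fold and 0.593-fold in gained peaks, and at 0.494-fold and 0.417-fold in spray-gained peaks.

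The dark list lacked peaks that the LD control list had at photosynthesis and flavonoid genes. Against the LD control, 10155 LD peaks (29.3%) had no dark counterpart and 4439 of 28917 dark peaks had no LD counterpart. The LD peaks missing in the dark touched 17 of 40 light harvesting and photosystem genes (mean 11, percentile 97.51) and 7 of 8 early light protection and flavonoid genes (mean 2.79, percentile 99.71). After 24 h of light the photosystem count was 12 (mean 13.2, percentile 27.04) and the flavonoid count 4 (mean 3.5, percentile 50.06). Peaks at 24 h without an LD counterpart numbered 4172 (15.6%) and reached 6 of 20 root markers (mean 1.58, percentile 99.67): SCR, SHR, GL2, MYB36, EIR1 and AUX1. Of these, SCR, SHR and AUX1 also lost an LD control promoter peak at 24 h. SCR, SHR and EIR1 also had a dark promoter peak without an LD counterpart. In the other direction 12092 LD peaks (34.9%) had no counterpart at 24 h. Other settings for promoter lists were tried on the main comparisons only, so the percentiles given here have no such check.

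The spray control differed from the LD control in about as many peaks as heat shock did. Gained peaks touched promoter windows of 35 of the 347 listed genes and lost peaks those of 43. Of the spray control's nuclear peaks, 5499 overlapped no LD control peak and 1365 of these (24.8%) had their midpoint in coding sequence, against 501 of 4962 heat-gained peaks. In promoter windows no single list reached the threshold. The highest was epidermis and trichome markers with 4 of 12 members that lost a peak (mean 1.24, percentile 97.46), and heat chaperones gained peaks at 2 of 30 (mean 3.16, percentile 15.82). Clock genes lost peaks at 0 of 17 (mean 3.74), as few as in 1.29% of random lists. Over transcribed spans, spray-gained peaks reached 6 of 12 genes of the unfolded protein response (mean 1.6, percentile 99.73), 4 of 8 early light protection and flavonoid genes (percentile 99.21) and 7 of 17 housekeeping genes (percentile 99.41).

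Genes named in advance had these promoter peaks. HSP101 had 1 peak in 6 lists and 2 after heat shock, and its best peak ranked by signal at percentile 30.8 of the LD control list, 45.7 of the spray control list and 96.9 of the heat shock list. HSP70 had 1 peak in every list, ranked at 42.1 in the LD control, 58.9 in the spray control and 92.2 after heat shock. These ranks hold within each list, and lists differ in length and possibly in depth. HSFA2, HSP18.2, the light regulator HY5, the clock gene CCA1, PIF3 and IAA19 had 1 peak in every list. LHCB1.1 had 0 in the dark and after 30 min and 1 in the other 5 lists. RBCS1A had 1 in the dark and 2 in every other list. ELIP1 had 1 in the light series and the LD control and 2 in the spray control and after heat shock. PORA, an enzyme of chlorophyll synthesis in seedlings leaving the dark, had 0 in the whole light series and 1 in each list of the heat series. TOC1 had 2 in 6 lists and 1 after heat shock. ACT2, an actin control, had 1 in the dark, after 30 min and after heat shock and 2 in the other 4 lists. CRA1, a seed storage gene, had 0 in every list.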

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

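All tests below were chosen as checks of an explanation after the patterns they address had been seen. Some of them use comparisons or settings that had been fixed in advance, such as the spray control and the upper part of a list by signal. For weak peaks, shared copies, the 2-unit element and lists of equal length, the outcome that would decide was set before the test's own result was seen. For the spray control, the dark library, moved positions, whole genes and the 3-unit element it was set after values that bear on the test had been seen.

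The spray control list held 242 peaks on the chloroplast genome and 232 on the mitochondrial genome, together 474 of 34254 peaks (1.38%). They stand out because the LD control list, and the other 5 lists, held 0 organelle peaks, and the comparisons leave the organelles out. The chloroplast peaks had a median signal of 122072 and the mitochondrial peaks 2856, against 1036 for nuclear peaks of that list. No explanation was tested; whether organelle peaks were removed from the other lists is not recorded in the labels.

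Heat shock brought gained promoter peaks at 9 of 30 heat chaperone genes, and each of these but HSP101 had one that also touched its transcribed span. The tables argue against these technical explanations: in the spray control the same list reached percentile 15.82, over the upper 50% by signal 8 genes remained (percentile 100), and without peaks that have another close match the percentile was 99.96. Peaks called at another position of the same open region may explain part of the promoter count, which was 5 (percentile 96.84) without peaks within 150 bp of an LD control peak, but not the peaks over whole genes, where 25 of 30 genes had one (mean of random lists 1.49, percentile 100). Binding of heat shock factors is a candidate explanation that the 3-unit element goes with over all gained peaks (3.66-fold). Of the 37 peaks with it, 23 were in the heat shock list only, and 1 touched the promoter window of a listed gene. This count covers gained peaks only, and 27 of 30 chaperone genes already had a promoter peak in the LD control. It therefore cannot decide whether the factors bind at the chaperone genes. In the upper 50% by signal 5 gained peaks held it (2.57-fold, percentile 95.37, under the threshold). The 2-unit element cannot be told apart from background because spray-gained peaks held it at 1.44-fold. Heat shock itself, which the design names, stays open as the biological explanation and would need replicate libraries.

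After 3 h of light, 13 of 40 light harvesting and photosystem genes gained a promoter peak. Of the 14 peaks, 2 were seen after 30 min and 11 were peaks in the LD control. This cannot decide whether weak peaks were missed in the dark library. The dark and 30 min lists were both shorter (28917 and 28824 peaks) than those of 3 h and the LD control (31336 and 34637). Shared copies (percentile 99.93 without peaks that have another close match) and moved positions (13 genes, percentile 99.96, without peaks within 150 bp of a dark peak) are argued against. The longer list at 3 h could account for part of the count: with lists of equal length it was 7 (mean 3.47, percentile 94.5), and all 14 peaks lay in the lower 50% by signal. Light, the treatment, stays open beside missed peaks and list length.

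After 3 h of light, 11 of 31 auxin and cell wall growth genes lost a promoter peak. Shared copies within the SAUR family (10 genes, percentile 99.92, without peaks that have another close match) and moved positions (10 genes, percentile 99.99, without peaks within 150 bp of a 3 h peak) are argued against as the whole cause. Peaks present by chance in the dark library could explain part of it, but the test cannot decide this. Of the 10 lost peaks, 5 were already absent after 30 min, when the seedlings had also had light, and 7 were peaks in the LD control. Light, the treatment, stays open beside it.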

How the results depend on the processing

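Settings chosen only after the results had been seen are named as such; the others were fixed in advance. Where a value moved, the cause was not tested, except where stated. Values are percent of peaks in the order heat shock against LD control, 30 min, 3 h and 24 h of light against dark, spray against LD control, dark against LD control and 24 h of light against LD control, each as gained and lost.

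A stricter overlap, at least 50% of the shorter peak, raised all shares by construction, to 22.2 and 26.4, 16.1 and 16.4, 25.7 and 19.5, 22.7 and 28.6, 22.6 and 24.6, 22.8 and 35.6, and 26.8 and 43.6. Listed genes that gained a promoter peak became 78 after heat shock, 43 at 30 min and 75 at 24 h. Those that lost one became 83 after heat shock, 61 at 3 h and 76 at 24 h. Percentiles under the threshold were 93.95 for auxin and cell wall growth gained after heat shock, 69.28 for light signalling gained at 3 h, 96.94 for photosystems gained at 24 h and 93.36 for auxin and cell wall growth lost at 24 h.

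Lists of equal length gave 15.66 and 15.64, 9.72 and 9.71, 13.4 and 13.3, 14.9 and 14.9, 14 and 14, 20.01 and 19.98, and 23.8 and 23.8. Equal gained and lost shares follow in part from equal length. Chosen after seeing the data, the same setting gave promoter shares of 60.6% in the dark, 61.5% at 30 min, 62.8% at 3 h, 61.3% in the LD control, 61.4% in the spray control and 59.9% after heat shock. It left 2 lists apart at 30 min, with auxin and cell wall growth gained after heat shock reversed at 31.18 and photosystems gained at 3 h at 94.5.

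Peaks in the upper 50% by signal, which exclude those near the calling threshold, gave 5.44 and 6.16, 2.06 and 2.3, 3.49 and 4.76, 3.5 and 6.12, 4.42 and 4.43, 8.15 and 9.51, and 9.62 and 15.5. Listed genes that gained and lost a promoter peak became 19 and 17 after heat shock, 3 and 7 at 30 min, 16 and 8 at 3 h, and 12 and 12 at 24 h. Lists apart numbered 2 at 30 min, 2 at 3 h and 1 at 24 h. The percentile reversed to 0, with a count of 0, for auxin and cell wall growth gained after heat shock and lost at 30 min, 3 h and 24 h, and for photosystems gained at 3 h and 24 h. Heat chaperones stood at 100 and early light protection at 99.99 (3 h) and 99.48 (24 h). Motif folds under the threshold were 1.26 for the 2-unit and 2.57 for the 3-unit heat shock element and 1.52 for the telo-box at 30 min, and the telo-box reversed to 0.602 at 3 h and 0.684 at 24 h.

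With the spray control as the reference, heat shock shares were 19.3 and 21.8. With both controls merged they were 10.5 and 26.8, the latter as a share of the merged control regions. For gene lists, lost peaks were taken otherwise, as LD control peaks that overlap a spray control peak and no heat shock peak. This gave 33 listed genes that lost a promoter peak. Gained and lost together, 5 lists stood apart, the 3 new ones being chaperones lost, early light protection lost and vascular markers gained.

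Counting only peaks with none of the other list within 150 bp, chosen after seeing the data, lowered all shares by construction, to 12 and 16.9, 8.38 and 8.5, 16.2 and 8.62, 9.03 and 14.8, 13.3 and 16.2, 11.7 and 26.7, and 11.5 and 31.4. After heat shock 30 listed genes gained and 35 lost a promoter peak and 0 lists stood apart, with chaperones gained at 96.84 and auxin and cell wall growth gained at 92.94. Light signalling gained at 3 h stood at 91.36.

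A window of 500 bp upstream to 100 bp downstream holds fewer peaks. Listed genes that gained and lost a peak became 30 and 33 after heat shock, 23 lost at 30 min and 39 gained at 3 h, with 1 list apart after heat shock and 2 at 3 h. Percentiles under the threshold were 94.01 for chaperones gained after heat shock, 93.97 for auxin and cell wall growth lost at 30 min, 78.25 for light signalling and 93.2 for early light protection gained at 3 h, and 91.01 for the latter at 24 h. The gene body with 1000 bp upstream gave 87 gained and 94 lost after heat shock, 40 gained and 2 lists apart at 30 min, and 96.11 for auxin and cell wall growth gained after heat shock.

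Counting each peak for 1 member, chosen after seeing the data, put auxin and cell wall growth gained after heat shock at 96.11. Random lists without matching put light signalling gained at 3 h at 89.59. Leaving out peaks with another close match, also chosen afterwards, put auxin and cell wall growth lost at 24 h at 96.06. Matching motif sets on signal and on 3 GC classes in place of 10, 2 changes at once and chosen afterwards too, gave 1.12 for the 2-unit heat shock element and reversed the telo-box at 24 h to 0.948; without matching the latter was 1.07.

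Heat chaperones gained after heat shock stood between 99.88 and 100 under the 8 settings other than the narrow window and the distance of 150 bp that were tried on them. Across all settings, 68 of 92 list percentiles stayed on their side of the threshold, 17 fell under it and 7 reversed. Of 30 motif folds 22 stayed, 5 fell under and 3 reversed. Of 74 peak shares 14 stayed within their interval and 60 moved, and of 66 totals of listed genes 42 stayed and 24 moved. Of 33 counts of lists apart 24 stayed and 9 moved. Of 532 values of named genes 404 stayed and 128 moved. Leaving out nuclear copies of mitochondrial DNA moved 0 of the 14 shares beyond its interval. No paired analysis was possible because each condition has 1 library. With 1 library per condition and no read depths used, the share of differences owed to depth cannot be given.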

Other observations

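The genes and regions below were chosen only after their values were seen, and no test in this part was fixed in advance.

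After heat shock, new peaks lay over chaperone genes outside the fixed list as well. HSP81-2 and HSP81-3, neighbouring cytosolic HSP90 genes on chromosome 5, gained 8 and 5 peaks over their spans. Of these 13 peaks 9 have another close genomic match, so their split between the copies is uncertain. The HSP70 family gene AT3G09440 and the mitochondrial MTHSC70-2 gained 4 each, and the chaperonin gene Cpn60beta2 gained 3. Of the 27 genes with at least 3 such peaks, 13 were listed chaperones, 5 were these others and 9 have no chaperone product in the annotation. Of the 9, AT5G12110, an elongation factor, gained 4. BRX, AT1G59865, AT1G68862, SCPL13, AT3G07090, AT4G09150, AT5G47830 and RIN3 gained 3 each. Signal differed between them: percentiles were 3.9 to 14.7 for BRX, 0.705 to 9.71 for RIN3 and 68.5 to 97.4 for AT1G59865. Gained peaks over the listed chaperones had a median percentile of 77. AT1G59865 is the neighbour of the listed chaperone HSP17.6A-CI, which gained a peak of signal 2209. Of the 13 genes with at least 4 such peaks, 8 were listed chaperones. No explanation for the peaks along genes outside the fixed list was tested, and the RNA-seq samples of the series were not analysed.

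Another group of genes had a new peak beside a lost one. Of all 4962 heat-gained peaks, 709 (14.3%) lay within 150 bp of a peak that heat shock lost, against 0.975% of retained peaks. In the spray control 581 of 5499 gained peaks (10.6%) did so, against 0.697% of retained peaks. In the top 10% by signal the share was 50.5% after heat shock (40.7 to 60.3%), 35.8% in the spray control (25.4 to 47.8%), 42.5% after 30 min of light (28.5 to 57.8%), 62.5% after 3 h (51 to 72.8%) and 70.8% after 24 h (59.5 to 80.1%). ECA4, a calcium pump gene, had a peak overlapping 2374881 to 2375030 on chromosome 1 in the 3 h, 24 h, spray and heat shock lists and one overlapping 2374701 to 2374850 in all lists but those of 3 h and the spray control. TPL had one overlapping 5421361 to 5421510 in the dark, 3 h, 24 h, spray and heat shock lists.

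A stretch of chromosome 2 from 3239038 to 3509765 copies the mitochondrial genome. It held 53 peaks in the dark, 47 after 30 min of light, 47 after 3 h, 48 after 24 h and 58 in the spray control, and 0 in the LD control and after heat shock. Beyond the end of this stretch, AT2G08986 (3618058 to 3626460) had the strongest peak gained in the spray control (signal 6203), at 3617181 to 3617330. That peak lay upstream of the gene and within the span of AT2G07981. Over their spans AT2G08986 gained 15 peaks in the spray control and AT2G07981 gained 6. The peaks over AT2G08986 were not particular to the spray control. Its span also held 15 peaks in the dark, 13 after 30 min and 12 after 3 h of light, and 0 in the LD control. No explanation was tested.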
